A study of Mus musculus with 12 samples.

How the data were processed

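Right ventricular free wall from Scn5a 1798insD/+ and wild-type mice of 2 strains was profiled on 12 one-colour chemiluminescent Applied Biosystems Mouse Genome Survey arrays, 3 per group. Groups and replicate numbers were taken from the sample titles. Per the labels, digoxigenin-labelled cRNA was made from total RNA, and the vendor's software corrected the signals for background and normalized them over the array surface. Per the labels, spots that the software marked as bad were removed, but each gene probe has a value in the deposited files. The deposited intensities came as a background-corrected signal and an assay-normalized signal per probe. Per the file headers, each probe also has a signal-to-noise score and a quality code, deposited as they left the software. The deposited table of the whole series equalled the assay-normalized signal of the sample files at all 33012 gene probes of every array. Its column medians were 1.09, 1.17 and 1.13 in 129P2 mutants, 1.19, 1.15 and 1.12 in 129P2 wild types, 1.1, 1.22 and 1.18 in FVB mutants, and 1.19, 1.57 and 1.24 in FVB wild types, on a linear scale, and no centring was seen.

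From these files the assay-normalized intensity was used without further background correction. The 303 control features were left out. Values with a quality code of 5000 or more were set to missing, 4749 values or 1.20% of all. The arrays were quantile normalized together and log2 was taken. A probe was tested when its signal-to-noise ratio was 3 or more on all its usable arrays of at least 1 group, which left 15760 probes. A probe missing on all arrays of a group has no value in the comparisons with that group. Different probes of a gene were tested separately.

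Identifiers were matched to the RefSeq table of GRCm38.p6 by accession without version or by symbol and synonym. Of the 33012 probes, 27930 carry a Celera identifier that the table does not hold, 311 matched by RefSeq accession and 6 by another name. The files name no genome build, so no coordinates are given. The gene lists fixed beforehand could not be tested because none had 5 measured members. The test of genes on either side of Scn5a within the window set beforehand could not be made either, because no named probe lies there.

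Group means of all 12 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with 8 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. Adjusted p under 0.05 was the threshold. The 6 comparisons were the strain difference in wild types and in mutants (129P2 minus FVB), the mutation in each strain (mutant minus wild type), the interaction and the mean of both mutation contrasts. Designs, alternatives and the naming rule were fixed before the data were examined. The rule names the 10 largest rises and falls among called probes with 1 gene symbol, detection on all arrays of a compared group and no overlap between replicates, and where fewer pass, all that pass and then the 10 named probes with the smallest p as values not called. For the fit without FVB wild-type replicate 2, the named genes that passed are given, a choice made after its values were seen. Where a probe was not above background on any array of 1 group, the fold is taken against a floor. The floor is the higher of the lowest detected signal and the probe's own signal on each array. A probe not above background can lie over the lowest detected signal, so this fold is not a lower bound. Where that fold equals the estimated fold, the log2 difference is given instead.

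The first characters of the array identifiers in the headers divide the arrays into 2 series, of 4 and 8 arrays. Whether these are manufacturing or hybridization batches is not given in the sources used here. The smaller holds 129P2 mutant replicate 1, FVB mutant replicate 2 and FVB wild-type replicates 2 and 3. Counts with the series as a block and within each series are in the closing section. A reverse transcription control index was computed per array as the mean log2 signal of the kit's control features numbered 1 and 2 less that of those numbered 5.

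The fit was tested on simulated data, drawn from the mean and SD of 15757 probes with the noise of each array, in which 200 probes were changed by 1.5-fold, 2-fold or 4-fold. For the mutation in 129P2, 0% of the probes changed 1.5-fold, 5.97% of those changed 2-fold and 42.4% of those changed 4-fold were recovered with 12 arrays, and 11.9%, 40.3% and 80.3% without FVB wild-type replicate 2. False calls were 0 in both. For the mutation in FVB, 7.46% and 31.8% were recovered at 2-fold and 4-fold with 12 arrays, and 29.9% and 74.2% without that array, with 0 and 2 false calls. For the strain in wild types the shares at 2-fold were 7.46% and 38.8%, and for the strain in mutants 5.97% and 46.3%. False calls there were 0 with 12 arrays, and without that array 2 of 87 calls in wild types and 6 of 102 in mutants. The interaction and the mean of both mutation contrasts were not simulated. Noise was drawn independently for each probe, so these figures do not cover variation that probes share, and real false calls may be more frequent.

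Alternatives covered the normalization, the source of the values, the detection filter, missing spots, a floor, the variance model, array weights, the arrays in the fit, the replicate number as a block, averaged probes, the threshold, each array left out and the array series.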

Results

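Gene expression was measured in the free wall of the right ventricle of male mice that carried the Scn5a 1798insD mutation on 1 allele and in wild-type mice, each on the 129P2/OlaHsd and on the FVB/NJ background. Scn5a encodes the main sodium channel of heart muscle cells, which carries the fast inward current of the action potential. The mice were labelled as 12 weeks old. Each of the 4 groups (129P2 mutant, 129P2 wild type, FVB mutant and FVB wild type) had 3 samples, and each sample was hybridised to 1 one-colour array, 12 arrays in all. The labels number the samples of a group as replicates without saying whether each came from a separate animal, so the p-values below measure the spread between these samples. The number of arrays limits the precision of every value.

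FVB wild-type replicate 2 stood apart from the other 11 arrays. Its signals had Spearman correlations of 0.61 to 0.68 with them across probes, against 0.94 to 0.99 among the other 11, and 38.0% of its gene probes had a signal-to-noise ratio of 3 or more, against 47.2% to 52.8% on the others. Against the mean of the other 2 FVB wild-type arrays, 2422 tested probes were over 8-fold lower on it and 144 over 8-fold higher. FVB wild-type replicates 1 and 3 differed by over 8-fold at 88 probes. The spike-in control features of the reverse transcription kit also differed on this array. Those numbered 1 had a median log2 signal of 8.03, against 15.07 to 15.88 on the other arrays, and those numbered 5 had 17.27, against 15.92 to 16.73. All 12 arrays entered the comparisons as planned before the data were examined. The median within-group SD was 0.51 on the log2 scale with the array and 0.26 without it. The main count of called probes of each comparison is therefore also given without it. So are the named differences that it moved by over 1.5 times, a choice made after its values were seen.

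**Figure D1:**
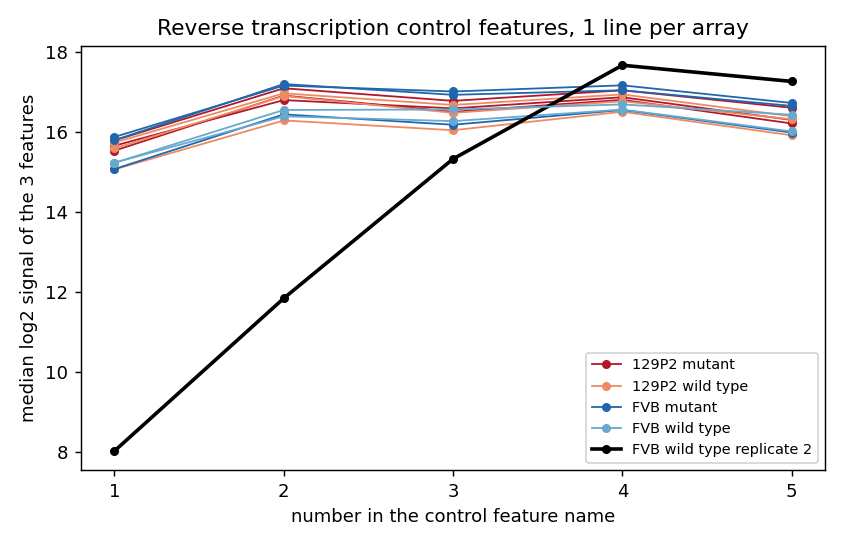
Median log2 signal (y axis) of the 3 reverse transcription control features of each number (x axis), with 1 line per array coloured by group. FVB wild-type replicate 2, in black, runs from 8.03 at number 1 to 17.27 at number 5, while the other 11 arrays lie between 15.07 and 15.88 at number 1.

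Most gene probes carry identifiers that the reference used here does not pair with a gene. Of 33012 gene probes 317 could be named, for 311 genes, and 162 of the 15760 tested probes had a name. The probe for the targeted gene, Scn5a, is not among the named ones, so no value is given for it and the labels were not checked against the mutated gene. None of the gene lists fixed beforehand had the 5 measured members that a list test needed. The tested members were Kcne4, an accessory subunit of potassium channels, Mfap4, a protein of the extracellular matrix, Hba-a1, an alpha-globin, H2-Q7, a class I histocompatibility antigen, and the transcription factor Jun. With all 12 arrays none of these 5 passed the threshold in any of the 6 comparisons.

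The first comparison asked how the 2 genetic backgrounds differed without the mutation. In wild-type hearts 91 probes were higher and 154 lower in 129P2 than in FVB, of 15757 tested (limma, adjusted p under 0.05), and 228 of these 245 differed by at least 2-fold. Leaving out 129P2 wild-type replicate 1, 2 or 3 gave 150, 109 or 98 calls, and a fit of the 6 compared arrays alone gave 7, all lower in 129P2. The named gene that passed was Dynlt1b, a light chain of the dynein motor. Its log2 signal was 7.67 ± 0.12 (SD, n = 3) in 129P2 and 5.60 ± 0.25 (SD, n = 3) in FVB, a log2 difference of 2.07 (SE 0.20, limma adjusted p = 0.000565), and all 3 arrays of 129P2 lay above all 3 of FVB. Dynlt1b belongs to a family of near-identical copies in the mouse, so its signal may include theirs. Of the other named probes the 10 with the smallest p did not pass. Their log2 differences were 1.26 (SE 0.30) for Rtl8c, 0.89 (SE 0.25) for 2700081O15Rik, -1.51 (SE 0.47) for Prr18 and 1.29 (SE 0.41) for Mfap4. Gprasp1 was at -1.03 (SE 0.34), Tcim at -0.71 (SE 0.25), Plin3 at 1.56 (SE 0.56) and Acyp2 at 0.36 (SE 0.13). Zfp945, not above background on any FVB wild-type array, was at 1.47 (SE 0.48). Nupr1l, not above background on any 129P2 wild-type array, was at -1.57 (SE 0.56). Leaving out FVB wild-type replicate 2 moved Gprasp1 to -0.63, Plin3 to 0.70, Nupr1l to -0.97 and Zfp945 to 1.24. Prr18 was above background on 1 of 3 129P2 wild-type arrays. The first characters of the array identifiers divide the arrays into 2 series, and what these mark is not stated. With the series as a block 35 probes were higher and 53 lower, and within the larger series 146 and 118, with 1 FVB wild-type array that is assumed to vary like the other groups, while the smaller holds no 129P2 wild type. Within the larger series the log2 difference of Dynlt1b was 1.93 (limma adjusted p = 0.00102).

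FVB wild-type replicate 2 decided much of this comparison. When it was left out, 394 probes were higher and 417 lower in 129P2, and 487 of these 811 differed by at least 2-fold. In that fit 9 named genes passed. Beside Dynlt1b (log2 difference 2.14), the genes higher in 129P2 were H2bc18, a histone H2B gene (1.13, SE 0.24, limma adjusted p = 0.0215), Ctdnep1, a phosphatase of the nuclear envelope (1.09, SE 0.17, limma adjusted p = 0.00316), Rtl8c, a gene derived from a retrotransposon (1.06, SE 0.27, limma adjusted p = 0.0418), Crip1, a small LIM-domain protein (0.85, SE 0.10, limma adjusted p = 0.000778), Plin3, a lipid droplet protein (0.70, SE 0.15), and Slc47a1, a transporter of organic cations (0.56, SE 0.13). Rnaset2b, a ribonuclease, was lower in 129P2, at 8.72 ± 0.18 (SD, n = 3) against 9.52 ± 0.01 (SD, n = 2), and so was Hsd17b10, a mitochondrial dehydrogenase (log2 difference -0.49, SE 0.12, limma adjusted p = 0.0462). Hsd17b10 lost its call when the control index was added as a covariate (limma adjusted p = 0.0884), and was not called with array weights on all 12 arrays (limma adjusted p = 0.0927). With all 12 arrays these 8 genes did not pass, with log2 differences of 0.62 for Ctdnep1, 0.51 for Crip1, 0.14 for Slc47a1 and 0.004 for Rnaset2b, and the opposite sign, 1.19, for Hsd17b10. H2bc18 and Rnaset2b have close relatives in the genome whose transcripts their probes may also bind.

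The second comparison asked the same with the mutation present, and its group means use none of the arrays of the first. In mutant hearts 65 probes were higher and 66 lower in 129P2 than in FVB, of 15760 tested (limma), and 124 of the 131 differed by at least 2-fold. Leaving out any 1 of the 6 compared arrays gave 60 to 72 calls, fewest without 129P2 mutant replicate 1, and a fit of these 6 arrays alone gave 616. Dynlt1b was again the named gene that passed, at 7.39 ± 0.08 (SD, n = 3) in 129P2 and 5.50 ± 0.32 (SD, n = 3) in FVB (log2 difference 1.89, SE 0.20, limma adjusted p = 0.00158). With the array series as a block 58 probes were higher and 54 lower, and within the larger series 166 and 158. Within that series the log2 difference of Dynlt1b was 1.74 (limma adjusted p = 0.000988). Within the smaller series, which has 1 array of each of the 2 groups and takes its spread from FVB wild-type replicates 2 and 3 alone, it was 2.18 and did not pass. The 10 named probes with the next smallest p did not pass, with log2 differences of 2.20 (SE 0.66) for Ccl19, 0.53 (SE 0.17) for H2bc13, 0.92 (SE 0.34) for H2bc18, 0.88 (SE 0.34) for Ctdnep1, 0.44 (SE 0.19) for Dhrs7b, -1.50 (SE 0.64) for H2-Q7, 0.60 (SE 0.30) for Slc47a1, -0.50 (SE 0.25) for Tcim, -1.34 (SE 0.69) for Bcl2a1b and -0.61 (SE 0.34) for Gprasp1. FVB wild-type replicate 2 is in neither group, but it widens the shared estimate of the spread. Without it 393 probes were higher and 441 lower, with 9 named genes, and 468 of these 834 probes differed by at least 2-fold. Ctdnep1 (log2 difference 0.88, SE 0.15), H2bc18 (0.92, SE 0.22), Slc47a1 (0.60, SE 0.11) and Ccl19, a chemokine that attracts lymphocytes (2.20, SE 0.51), were higher in 129P2. Rnaset2b (-0.82, SE 0.11), Hsd17b10 (-0.47, SE 0.11), H2-Q7 (-1.50, SE 0.36) and the deubiquitinase Otub1 (-0.48, SE 0.12) were lower. The signal of H2-Q7 in FVB mutants was spread widely, 7.49 ± 0.93 (SD, n = 3). Ccl19 was above background on 1 of 3 FVB mutant arrays, where its signal was 0.34 ± 1.32 (SD, n = 3), so the size of its difference rests on values near background. Ccl19 and H2-Q7 also belong to families of close copies.

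**Figure D2:**
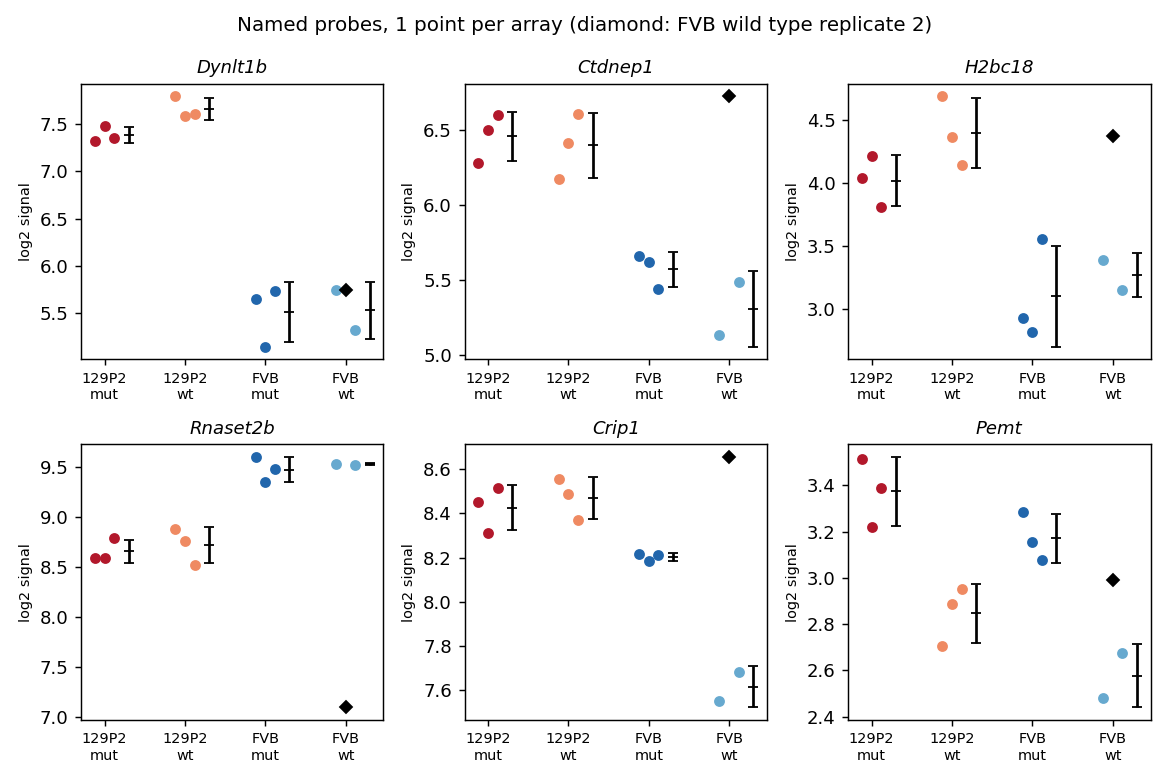
Quantile-normalized log2 signal (y axis) of 6 named probes in the 4 groups (x axis), with 1 point per array. The bar beside each group is the mean ± SD without FVB wild-type replicate 2, which is drawn as a black diamond. Dynlt1b separates the strains on all 12 arrays, while for Rnaset2b, Ctdnep1, H2bc18 and Crip1 the diamond lies away from the other 2 FVB wild-type arrays.

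Many strain differences were shared by both genotypes. Of the 245 probes called in wild types, 242 differed in the same direction in mutants, against 64.8% of all 15757 probes. Both comparisons called 52 higher and 62 lower, where 0.38 and 0.65 would be shared by independent lists, and none was called in opposite directions. The lists share the normalization and the estimate of the spread, so they are not fully independent and such baselines may be too low. When FVB wild-type replicate 2 was left out, the shared calls were 252 higher and 277 lower, against 9.83 and 11.7 for independent lists. In that fit 529 of the 811 probes called in wild types were also called in mutants. Crip1, Rtl8c and Plin3 were called in wild types but not in mutants, and Ccl19, H2-Q7 and Otub1 in mutants but not in wild types. Each differed in the same direction in the other genotype. In mutants Plin3 had a log2 difference of 0.48 (SE 0.14). The mutant means in 129P2 and FVB were 8.43 and 8.20 for Crip1 and 3.34 and 2.81 for Rtl8c. No interaction passed in that fit, so these calls do not establish a strain difference limited to 1 genotype. Across all 15757 probes the log2 differences of both comparisons had a Pearson correlation of 0.50, and of 0.71 without that array. These are correlations across probes, which are not independent replicates. The largest shared differences were at probes without a gene name here. With all 12 arrays mCG14703.1 was 115-fold higher in 129P2 wild types against the floor of the lowest detected signal (log2 difference 7.165, SE 0.59). In mutants its log2 difference was 5.885 (SE 0.59), with no FVB mutant array above background. The log2 differences of mCG65769.2 in wild types and mutants were 5.37 (SE 0.48) and 4.83 (SE 0.48), with a signal above background on 1 of 3 FVB wild-type arrays. Against the same floor the probe of mCG141044 was 263-fold and 123-fold lower in 129P2 in wild types and mutants. That of mCG146258, not above background on any 129P2 array, had log2 differences of -6.84 (SE 0.41) and -6.56 (SE 0.41). Without FVB wild-type replicate 2 these folds in wild types were 77.4 for mCG14703.1 and 206 for mCG141044, and mCG146258 was 144-fold lower. The floor was used where a probe was not above background on any array of the dimmer strain. These folds are not lower bounds, since probes not above background can lie over the lowest detected signal. Nupr1l, not above background on 129P2 wild-type replicate 1, had a log2 signal of 1.07 there. The mean of mCG141044 in 129P2 wild types was -1.72.

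**Figure D3:**
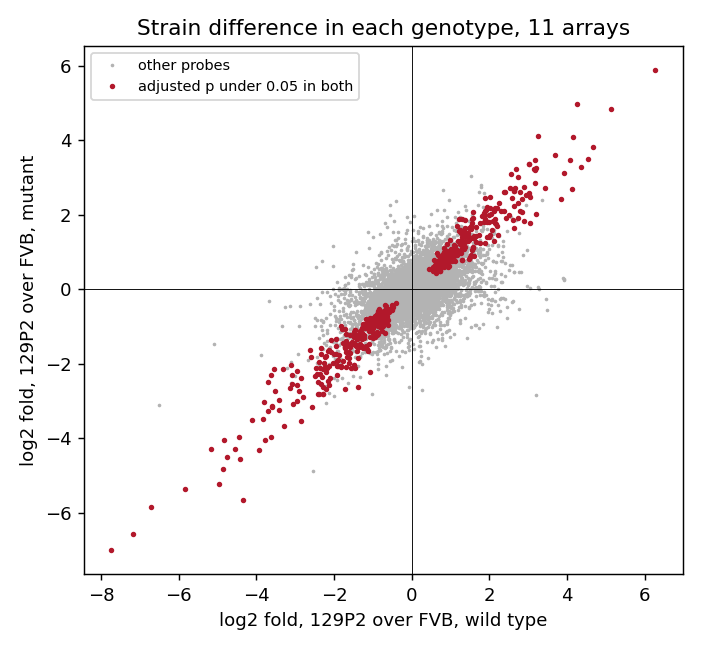
Log2 fold of 129P2 over FVB in wild types (x axis) and in mutants (y axis) for each tested probe, without FVB wild-type replicate 2. Red points are the 252 probes higher and 277 lower in both comparisons, and grey points are the other probes.

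The third comparison asked what the mutation changed in 129P2 hearts. No probe of 15757 passed (limma, smallest adjusted p = 1), and 203 had an unadjusted p under 0.05, where 788 would be expected by chance. With FVB wild-type replicate 2, which is in neither group, left out, none passed and 718 had an unadjusted p under 0.05. With that array kept and 129P2 wild-type replicate 1 left out, the count fell from 203 to 107. It was 991 with array weights and 677 with only the arrays compared. In a single simulated draw each, a true 2-fold change in this comparison was recovered at 5.97% of 67 changed probes with 12 arrays. Without FVB wild-type replicate 2 it was recovered at 40.3% of 67. The named probes with the smallest p are given as values that did not pass. Bhlha9, a helix-loop-helix factor, had a log2 difference of 1.57 (SE 0.62), with a signal above background on 2 of 3 wild-type arrays. Pemt, a methyltransferase of phosphatidylcholine synthesis, was at 3.37 ± 0.15 (SD, n = 3) in mutants and 2.85 ± 0.13 (SD, n = 3) in wild types, a log2 difference of 0.53 (SE 0.22). Grap was at -0.48 (SE 0.29), Frat2 at -1.10 (SE 0.71), Akap7, an anchor of protein kinase A, at -0.56 (SE 0.38), Zfp146 at -1.41 (SE 0.95), Ccl21b at -0.56 (SE 0.38), Ccdc166 at -0.49 (SE 0.34), Dynlt1b at -0.28 (SE 0.20) and Peg12 at -1.41 (SE 1.10). Frat2, Zfp146 and Peg12 were above background on 2 of 3 mutant arrays.

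The fourth comparison asked the same in FVB hearts, where the wild-type group holds the array that stood apart. No probe of 15760 passed (limma, smallest adjusted p = 0.438), and 1026 had an unadjusted p under 0.05. None passed without FVB wild-type replicate 2 either, and 925 had an unadjusted p under 0.05. These counts moved with single arrays, to 4278 and 3649 without FVB wild-type replicate 1 or 3 and to 399 and 373 without FVB mutant replicate 1 or 2. The fit without FVB wild-type replicate 3 passed 1 probe and array weights 2. The larger series, with 1 FVB wild-type array assumed to vary like the other groups, passed 2. The smaller passed 43, but holds 1 FVB mutant array and takes its spread only from the difference between FVB wild-type replicate 3 and the array that stood apart. A true 2-fold change in simulated data, from a single draw each, was recovered at 7.46% of 67 changed probes with 12 arrays. Without FVB wild-type replicate 2 the share was 29.9% of 67. The named probes with the smallest p did not pass either, with log2 differences of 0.93 (SE 0.30) for Rtl8c, -1.52 (SE 0.55) for Nars2, 0.64 (SE 0.25) for 2700081O15Rik, -0.48 (SE 0.19) for Dhrs7b, 1.61 (SE 0.64) for H2-Q7, 0.76 (SE 0.30) for Gga1, -0.49 (SE 0.20) for Snap47, -0.60 (SE 0.25) for Ddx28, 1.41 (SE 0.59) for Heg1 and -0.79 (SE 0.33) for Eola1. Without the array that stood apart, 7 of these were smaller by over 1.5 times, at -0.86 for Nars2, -0.31 for Dhrs7b, 0.79 for H2-Q7, 0.49 for Gga1, -0.30 for Ddx28, 0.57 for Heg1 and -0.40 for Eola1. Nars2 was above background on 2 of 3 arrays of both FVB groups. In that fit Crip1 had the smallest p, at 8.20 ± 0.02 (SD, n = 3) in mutants and 7.62 ± 0.09 (SD, n = 2) in wild types (log2 difference 0.59, SE 0.10, limma adjusted p = 0.771).

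Whether the mutation acted differently in the 2 backgrounds was tested as an interaction. No probe of 15757 passed (limma, smallest adjusted p = 0.8), and 206 had an unadjusted p under 0.05, or 373 without FVB wild-type replicate 2, 761 and 534 without FVB wild-type replicate 1 or 3, and 128 without FVB mutant replicate 1. In the fit without FVB wild-type replicate 3, 1 probe passed, and within the larger series, again with 1 FVB wild-type array, 2. The log2 difference of differences was -0.36 (SE 0.18) for Acyp2, an acylphosphatase, 1.37 (SE 0.71) for Zfp60, -0.64 (SE 0.35) for 2700081O15Rik, 1.22 (SE 0.67) for Prr18, -0.46 (SE 0.26) for Hba-a1, -0.71 (SE 0.41) for Grap, -2.69 (SE 1.56) for Peg12, -0.73 (SE 0.43) for Rtl8c, -1.46 (SE 0.90) for H2-Q7 and -1.25 (SE 0.79) for Vmn1r212, and none of these passed. Without FVB wild-type replicate 2 the values were 0.76 for Zfp60, -1.69 for Peg12, -0.64 for H2-Q7 and -0.58 for Vmn1r212. Crip1, with the smallest p of the named probes in that fit, was at -0.63 (SE 0.14) and did not pass. Prr18, Zfp60, Grap, Peg12 and Vmn1r212 were not above background on all arrays of every group.

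Averaged over both strains, the mutation changed no probe of 15757 past the threshold (limma, smallest adjusted p = 0.665), and 819 had an unadjusted p under 0.05. Without FVB wild-type replicate 2 none passed (smallest adjusted p = 0.328), and 1486 had an unadjusted p under 0.05 against 788 expected by chance. With other single arrays left out this count lay between 351, without FVB mutant replicate 2, and 1791, without FVB wild-type replicate 3. Pemt had the smallest p among the named probes, with a log2 difference of 0.49 (SE 0.15), or 0.56 (SE 0.11) without that array, and did not pass. Bhlha9, whose probe was not above background on any FVB wild-type array, is given no fold here. Rtl8c was at 0.56 (SE 0.22), Gga1 at 0.54 (SE 0.21), Akap7 at -0.67 (SE 0.27), Snap47 at -0.33 (SE 0.14), Nars2 at -0.90 (SE 0.39), Dhrs7b at -0.28 (SE 0.13), Ddx28 at -0.36 (SE 0.18) and Eola1 at -0.48 (SE 0.23). The last 2 and Nars2 moved to -0.21, -0.29 and -0.58 without FVB wild-type replicate 2. Without FVB mutant replicate 3, 5 probes passed, without FVB wild-type replicate 3, 1 probe passed, and within the larger series, with 1 FVB wild-type array, 2. With arrays weighted by how closely they followed their group, 37 probes were higher and 2 lower in mutants, none of them named. Recovery was not simulated for the interaction or for the mean of both strains.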

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

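Alternatives that leave FVB wild-type replicate 2 out together with another choice, the fits within 1 array series, and the signal before assay normalization were chosen after seeing the data. The other correlation, probe choice and windows set for the list and flank tests were not run, because no list had 5 measured members and the planned flank window held no named probe. The series table gave identical values. Calls for the mutation in 129P2 were 0 in every alternative run. Leaving out each array in turn gave 98 to 811 calls for strain in wild type, 60 to 834 for strain in mutant, 0 to 1 for mutation in FVB and for the interaction, and 0 to 5 for mutation over both strains. The highest strain counts came without FVB wild-type replicate 2. Strain calls in wild type and in mutant were 1721 and 1448 with array weights, 7 and 616 with only the arrays compared, 153 and 77 with the replicate block, 435 and 198 at adjusted p under 0.10, and in wild type 88 with the array series as a block. No pairing of the samples by replicate number was seen. Deviations of same-numbered arrays correlated at -0.40 to 0.20, and 2 of 12 arrays correlated best with their own number. This check cannot exclude a pairing, because other variation that arrays share enters the same correlations. With FVB wild-type replicate 2 left out, strain calls in wild type and in mutant were 901 and 952 with the control index as covariate. They were 670 and 868 with the array series as a block, and 802 and 831 when it was left out before normalization. Array weights gave 2 calls for mutation in FVB and 39 for mutation over both strains. The larger array series alone gave 324 calls for strain in mutant, 2 for mutation in FVB, 2 for the interaction and 2 for mutation over both strains. The smaller series, whose 1 residual degree of freedom is the difference between FVB wild-type replicates 2 and 3, gave 0 for strain in mutant and 43 for mutation in FVB. Apart from the arrays left out, the causes of these moves were not tested.

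Among strain calls in mutant 49.6% were higher in 129P2, and 54.3% to 55.2% with cyclic loess, median scaling or no further normalization. In wild type the share was 37.1%, and it crossed 50% with the setting. It was 28.5% with no further normalization, 0% of 7 calls with only the arrays compared, 51.9% with array weights, 55.3% in the larger series, and, with FVB wild-type replicate 2 left out, 48.6%, or 53.1% with the index and 50.7% with the series block. In mutant it was lowest, at 41.7%, without 129P2 mutant replicate 1. Without further normalization the median log2 difference over all probes was -0.25 for strain in wild type, -0.26 for mutation in FVB, 0.30 for the interaction and -0.11 for mutation over both strains. With cyclic loess it was 0.12 for strain in wild type, and with median scaling 0.12 for the interaction.

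In wild type the strain difference of Rnaset2b turned negative with median scaling (-0.21), no further normalization (-0.42), array weights (-0.85), the array series as a block (-0.33) and the larger series alone (-0.81). Leaving out each array in turn, it ranged from -0.806 to 0.413. With FVB wild-type replicate 2 left out it was -0.77 with the index, -0.86 with the series block and -0.78 before normalization. Hsd17b10 turned to -0.51 with array weights, -0.62 in the larger series, and -0.45, -0.55 and -0.47 in those same 3 fits, and ranged from -0.488 to 2.101 with each array left out. Slc47a1 turned to -0.15 with median scaling, -0.36 with no further normalization and ranged from -0.092 to 0.555 with each array left out, highest without FVB wild-type replicate 2. Crip1 and Acyp2 turned to -0.033 and -0.15 with no further normalization, where the interaction of Acyp2 turned to 0.18. Dynlt1b kept its sign in 34 alternatives in wild type (1.62 to 2.22, adjusted p up to 0.0759) and 35 in mutant (1.70 to 2.18). It lost its call in wild type with no further normalization and with only the arrays compared, and in mutant with no further normalization and in the smaller series. The signal over background limits probes near the detection threshold.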

Other observations

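Tests on the control index of FVB wild-type replicate 2, on the array series, on the index as a covariate, between genotypes and reassigned within groups, and on strain variants were chosen after the result was seen. Detection of the named probes was counted by gene family, without a test of the differences. The detection criterion was met by 3 of 39 olfactory receptor probes (7.69%, exact 95% interval 1.62% to 20.9%), 2 of 12 vomeronasal receptor probes (16.7%, 2.09% to 48.4%) and 2 of 7 keratin-associated protein probes (28.6%, 3.67% to 71.0%), against 155 of 259 other named probes (59.8%, 53.6% to 65.9%).

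FVB wild-type replicate 2 stands apart from the other 11 arrays. The median log2 signal of all its labelling and hybridization control features was 16.01, above the 15.12 to 15.88 of the others, which argues against a failure of labelling and hybridization as a whole. That median pools classes that moved apart, and does not bear on reverse transcription alone. Of the probes that distinguish the strains in mutants, a share of 0.601 (95% interval 0.567 to 0.635) lay nearer to the FVB mean on this array. It was 0.903 and 0.927 on the other 2 FVB wild-type arrays and 0.038 to 0.152 on the 129P2 wild-type arrays. This argues against a 129P2 sample under the wrong label, but weakly. Probes of 1 array are not independent, and the interval does not cover a distortion that they share. Its control index was -8.03, against -1.59 to -0.96 on the other arrays, consistent with short cDNA in its reverse transcription, although the files do not say which end of the control transcript each number marks. Whether the RNA itself was degraded stays open, and no biological explanation was tested.

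A hypothesis is that a milder form of the same gradient runs through the other arrays. Among those 11 arrays 571 probes rose and 94 fell with the control index within groups (limma), and of 100 assignments of the index within groups, the real one included, 1 gave as many as 665. The highest other gave 406. Probes that rose with the index had a median deviation of -1.48 on FVB wild-type replicate 2 and probes that fell with it 1.08, a difference of -2.56, against -0.59 to 1.09 for 1000 random probe sets. The same gradient may therefore act on all arrays to different degrees. Array brightness was not separated from the index, and the random sets were not matched for signal. Low indices of -1.46 and -1.43 fell on dim arrays (median signal 319.9 and 335.7), but the lowest, -1.595, fell on one at 449.8.

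The mutation folds of both strains correlated across probes, with r = 0.134 with all 12 arrays and 0.267 without FVB wild-type replicate 2, although they share no arrays. The control index was higher in mutants in both strains, by 0.134 in 129P2 and 0.235 in FVB, against group SDs of 0.118 to 0.215 with n of 2 or 3. Over both strains the difference was 0.184, which an exact permutation test within strains did not separate from chance (two-sided p = 0.145, 200 assignments). Corrected with the index slope of the other strain, a step after which both folds draw on arrays of both strains, the correlation was 0.019, but with the index reassigned within groups it was as low in 29 of 100 assignments, the real one included (median of the other 99, 0.274). Whether the index accounts for the shared part of the mutation folds therefore stays open, as does a common effect of the mutation, and with the index as covariate 1009 probes had an unadjusted p under 0.05 over both strains in these 11 arrays, against 1486 without it and 788 expected by chance.

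In wild types 811 probes differed between the strains without FVB wild-type replicate 2 and 670 with the array series as a block, 574 of them in common, which argues against the series as the whole source and leaves a part open. With all 12 arrays the count was 245, and 88 with the block. In mutants, where the series is balanced over the strains, the calls without that array were 834, and 952 with the control index as covariate, which argues against the index as the whole source. Sequence variants of the strains under the probes stay open, and the 47.1% of these calls that were higher in 129P2 decide nothing without probe sequences, which were not used here.

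Other splits of the arrays were counted with all 12 arrays. For strain in wild type the real split gave 245 calls and the highest other 0, and for strain in mutant 131 and 0. In each, 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For the other comparisons the real count was 0, which any split meets, so the splits decide nothing about them. These were 10 of 10 splits for mutation in 129P2, with a highest other of 0, 10 of 10 for mutation in FVB, with a highest other of 1, and 100 of 100 each for the interaction and for mutation over both strains, with a highest other of 0.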
